A study of Rattus norvegicus with 15 samples.

How the data were processed

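Messenger RNA was measured in whole blood from 15 samples, 3 in each of 5 groups. Per the labels' protocols, blood was collected in PAXgene tubes, which preserve RNA at the time of drawing, and libraries were made from 1 ug of total RNA with an NEBNext Ultra RNA kit and sequenced as read pairs of 150 bp. Bowtie 0.12.2 and the genome build Rnor_6.0 are named in the submitters' processing notes, without their role. The aligner settings, the counting tool, the strand setting, the annotation and the treatment of reads that match several places are not given in the sources used here. Reads shared between near-identical gene copies or overlapping gene models can therefore not be told apart from reads of a single gene.

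The deposited table is a signal that the authors made by dividing reads per feature by a factor for each library. This was worked out from the values, since the method is not given in the sources used here: in each library every value was a whole multiple of a single step, 100% of values within 0.01 of a whole number and at most 0.00276 from it. In sham replicate 1 the step is near 1, so that a division there changes the values little and its recovery is less well tested. Factors recomputed from the recovered reads by the median-of-ratios method differed from the deposited ones by at most 2.54e-08%. This scaling sets the median feature equal between libraries, so a change shared by most features would not appear in it, and a library with few reads on the median feature has all its abundant features scaled up.

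The table held 17599 features, 15043 with annotated IDs and 2556 with IDs of assembled models. The reference table of gene symbols (GRCr8 assembly) matched 0 of the IDs, and the files do not pair them with names. The 26 gene lists fixed before the data were examined (blood cell types, coagulation, inflammation, interferon response and others), their set tests and the rule for naming genes by symbol could therefore not be run (0 lists tested). In place of that rule, at most 2 features that rose and 2 that fell are printed by ID: among annotated features past adjusted p 0.05 whose groups do not overlap and whose mean over all libraries lies in the upper part of the tested features, the largest rise at 6 h, the largest further rise at 12 h, the largest fall at 1 h and the largest further fall at 6 h. This replacement was chosen after the data were examined. Circular RNA, which the series title concerns, was not analysed here.

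Features with a value of at least 10 in at least 3 libraries were tested, 11117 in all (8918 annotated, 2199 assembled). Since the values are not whole counts, the test was limma 3.58.1 (trend and robust) in R 4.3.3 on log2(value + 1), two-sided, with all 15 libraries in 1 fit and Benjamini-Hochberg adjustment over the features tested at a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low features. The 6 comparisons and the contrast of 6 h and 12 h with 1 h and 72 h were set before the data were examined. Run label could not be a term because each group carries a single label. Quasi-likelihood tests of edgeR 4.0.16 and tests of DESeq2 1.42.0 on the recovered reads were set as further tests before the data were examined. edgeR was run on the 11117 features. DESeq2 was run on all features with reads in any library and applied its own filter for low features. Its counts therefore differ from the others by the features entered as well as by the test. Other alternatives were the replicate number as a block, fits to the libraries compared alone, each library left out, other filters and pseudocounts, quantile normalization, limma without trend, and a 2-fold minimum. TMM scaling, the log2 library factor as a covariate, the 5 dominant features left out with equal totals, array weights and a fit within run label A&B were added after the data were examined. Shares of reads were compared by exact permutation tests within run labels and by permutation tests with 100000 resamples over all groups. Simulations of unchanged groups that share the sham libraries (100 draws) gave the values to set beside overlaps of lists and beside the levels of called features at other times, and those for lists of fixed size were added after the data were examined. A comparison of 3 against 3 values cannot give a two-sided exact p below 0.1.

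The recovered depth was 29.2 to 43.3 M reads (mega-reads) per library, of which 4.67 to 7.65 M lay outside the 5 features that each took more than 1% of reads on average. The limma fit was tested on simulated data for 6 h against sham, with 11117 features drawn from the real means and 50 features changed at each fold. Without a library axis it recovered 2% of 2-fold, 50% of 4-fold, 76% of 8-fold and 88% of 16-fold changes and called 6 unchanged features. With a library axis from fitted slopes added, it recovered 0% of 2-fold, 24% of 4-fold, 60% of 8-fold and 84% of 16-fold changes. It then called 0 unchanged features. With the log2 library factor in the fit it recovered 2%, 46%, 70% and 86% and called 5 unchanged features, and edgeR recovered 0%, 22%, 56% and 84% and called 1. The simulated spread was estimated from the groups alone and so already held the axis, which was thus counted more than once. The loss with the axis and the gain from the factor in the fit need not hold in the data. In these simulations nearly all changes of 2-fold went uncalled.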

Results

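Whole blood of male Sprague-Dawley rats, an outbred laboratory stock, was profiled by RNA sequencing in a model of deep venous thrombosis, in which a clot forms in a deep vein. The libraries fall into 5 groups of 3: sham, which the labels place at 0 h, and rats sampled 1 h, 6 h, 12 h and 72 h (3 days) after modelling. The question the design addresses is how blood transcripts differ from sham at each time. Sham, 1 h and 72 h carry the run label A&B (9 libraries) and 6 h and 12 h carry the run label C (6 libraries), so a difference of 6 h or 12 h from sham cannot be told apart from a difference between run labels. The labels number the replicates without naming animals, and p-values therefore measure only the spread between these samples, which may be technical. Features are annotated genes or gene models assembled from the reads. The files do not pair the IDs with gene names, so no gene is named and features are described by number, abundance, direction and time course.

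The whole reads recovered from the deposited values came to between 29.2 and 43.3 M (mega-reads) per library. Group means were 33.7 M ± 3.40 in sham, 34.1 M ± 2.52 at 1 h, 37.9 M ± 4.95 at 6 h, 34.7 M ± 2.65 at 12 h and 29.9 M ± 0.961 at 72 h (SD, n = 3 each). Between 11709 and 14524 features had reads in a library. Most reads fell on 5 assembled features, which together took 79.3 to 85.1% of each library. The reads left for all other features numbered 4.67 to 7.65 M per library. Libraries of the same group correlated on the log2 scale with a median r of 0.888 (0.787 to 0.920) across genes, against 0.866 (0.792 to 0.916) for libraries of different groups; genes are not independent replicates. As a check for repeated libraries, counts were compared between all pairs, and the lowest chi-square per degree of freedom was 28.5. This check covers counting error only and says nothing of the spread between samples.

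The most abundant feature took 49.4% of reads on average, with 54.5% ± 3.60 in sham, 50.5% ± 2.38 at 1 h, 44.8% ± 1.27 at 6 h, 45.7% ± 4.44 at 12 h and 51.5% ± 2.69 at 72 h (SD, n = 3). Its share differed over the 5 groups by a permutation test before adjustment (p = 0.0121) and did not after Benjamini-Hochberg adjustment over 18 tests (0.218). Within run label A&B the exact permutation p was 0.343, and between 6 h and 12 h it was 0.8. The features ranked 3 and 4 by abundance together took 8.59% ± 4.10 in sham, 18.4% ± 1.86 at 1 h, 17.5% ± 2.68 at 6 h, 14.7% ± 5.87 at 12 h and 12.6% ± 4.77 at 72 h (SD, n = 3). Every 1 h library lay above every sham library. The exact permutation test over sham, 1 h and 72 h gave p = 0.0429 (adjusted 0.352), and the permutation test over all 5 groups gave p = 0.0870 (adjusted 0.352). The feature ranked 2 took 19.5% ± 2.44 in sham and 13.7% ± 0.939 at 1 h (SD, n = 3), with an exact permutation p of 0.111 over sham, 1 h and 72 h (adjusted 0.352). None of these shares passed after adjustment.

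**Figure D1:**
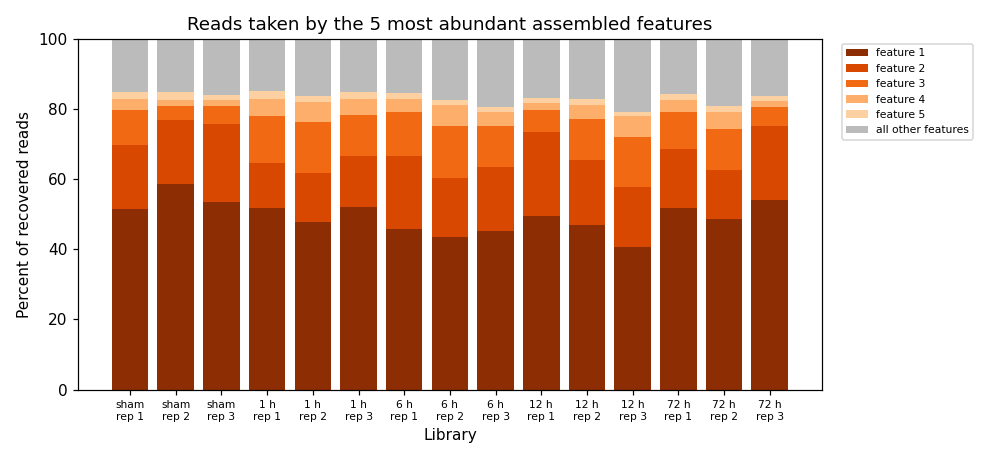
Percent of recovered reads (vertical axis) taken by each of the 5 most abundant assembled features and by all other features in each of the 15 libraries (horizontal axis, by group and replicate). The 5 features together take 79.3 to 85.1% of every library, and the most abundant takes 40.8 to 58.6%.

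Libraries of a group differed widely in the factor by which the deposited values had been scaled. The factor ran from 0.584 in 12 h replicate 2 to 2.67 in 12 h replicate 3, although these libraries held 31.8 and 36.9 M reads. The former had reads on 11709 features and the latter on 14524. The first principal component of the tested features, with 25.1% of the variance, followed the log2 factor with Pearson's r = -0.86 (permutation p = 2e-05, adjusted 8e-05 over 4 relations) and Spearman's rho = -0.879 (permutation p = 5e-05, adjusted 0.0002) over the 15 libraries. Without the 2 libraries farthest from the median factor r was -0.853. Within run labels A&B and C it was -0.952 and -0.995. The factor itself did not differ detectably between the 5 groups (permutation p = 0.932, adjusted 0.932). Of the variance of the component 35.0% lay between groups, against 7.95% of that of the log2 factor. Random groups of 3 libraries would also hold a sizeable part of the variance between them. The share of the component was not tested against that, so it is no evidence of a group difference. At adjusted p under 0.05 in limma, 3750 of 11117 features followed the factor, 1676 rising and 2074 falling with it. The median slope was 0.45 log2 units per unit of log2 factor in the least abundant of 4 equal parts of the features and -0.42 in the most abundant part. It was -1.07 for the 100 most abundant features. The values are reads divided by this factor, while total reads varied far less, so abundant features fall with it in part by construction. The permutation p-values and the count of features that followed the factor do not remove this.

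**Figure D2:**
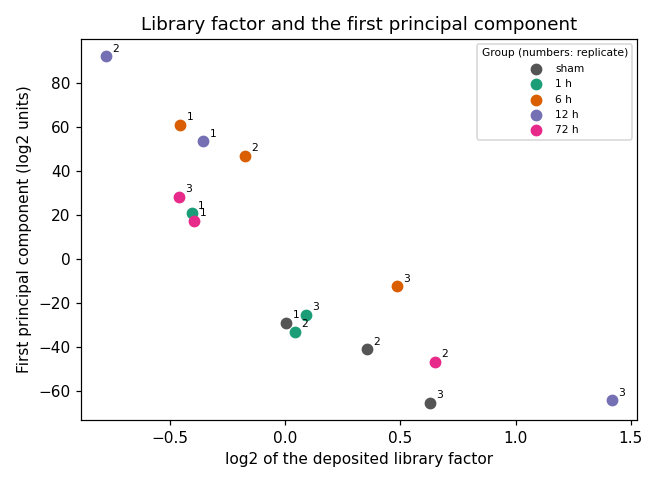
First principal component of log2 values (vertical axis, log2 units) against log2 of the deposited library factor (horizontal axis) for the 15 libraries, coloured by group and numbered by replicate. The component falls as the factor rises (r = -0.86), and libraries of the same group lie far apart, most so 12 h replicates 2 and 3.

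At 1 h, 15 of 11117 features were past adjusted p 0.05 against sham in limma, and all 15 were lower. Their log2 differences had a median size of 2.43 and ran from 1.57 to 4.72. For each of the 15, all 3 libraries at 1 h lay below all 3 sham libraries. Over all tested features 20.9% separated the groups completely, where chance gives 10%. Here and below, this 10% is a mean over all splits of the libraries. Features vary together, so a single split can lie far from it, and departures from it were not tested. The annotated feature with the deepest fall by the selection rule, ENSRNOG00000001806, had a normalised read count of 127 ± 17.7 in sham and 10.2 ± 9.67 at 1 h (SD, n = 3), a log2 difference of -3.87 (SE 0.622, limma adjusted p = 0.0281). Its count was 12.0 ± 1.78 at 6 h, 80.1 ± 83.3 at 12 h and 43.8 ± 6.89 at 72 h (SD, n = 3), where the log2 difference from sham was -1.52 (limma adjusted p = 0.632). The median log2 difference of the 15 features was 0.14 at 6 h, 0.44 at 12 h and -0.94 at 72 h, and 14 of the 15 were below sham at 72 h, where none passed the test. Since all times share the sham libraries, simulated unchanged groups also lay below sham at 72 h in a median of 14 of 15 features (12 to 15 in 100 simulations). At 6 h and 12 h 7 and 6 of the 15 were below sham, fewer than the simulated 10 to 15 and 11 to 15. The simulated features vary independently, which real ones do not, so these ranges are too narrow. Libraries at 6 h and 12 h also carry another run label than sham, so a return to the sham level is not shown. Among the 15, 5 were assembled models, a share of 33.3% against 19.8% of the features tested (Fisher's exact p = 0.195, adjusted 0.264). edgeR on the recovered reads called 0 features at 1 h (784 at unadjusted p under 0.05, against 810 in limma) and DESeq2 called 80, of which 69 were lower, and with the 5 dominant features left out and libraries set to equal totals limma called 0 (628 at unadjusted p under 0.05). The count was 3 (2 higher, 1 lower), 0 and 0 without sham replicate 1, 2 and 3, and 10 (all lower, 5 of them among the 15), 1 and 0 without 1 h replicate 1, 2 and 3, and ENSRNOG00000001806 had an adjusted p of up to 0.280 over its alternatives.

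At 6 h, 54 features differed from sham in limma, 37 higher and 17 lower, the largest number among the 4 times by this test. That order depends on the weight given to single libraries. Without 12 h replicate 3 limma called 1546 at 12 h, and with array weights it called 1223 at 6 h and 3604 at 12 h. Their log2 differences had a median size of 2.77 and ran from 1.5 to 6.22. All 54 separated the 3 libraries at 6 h from the 3 sham libraries, as did 27.9% of the features tested, where chance gives 10%. ENSRNOG00000013973 rose from a normalised read count of 27.3 ± 18.9 in sham to 607 ± 512 at 6 h (SD, n = 3), a log2 difference of 4.31 (SE 0.868, limma adjusted p = 0.0432). ENSRNOG00000030404 fell from 311 ± 21.4 in sham to 18.2 ± 2.79 at 6 h (SD, n = 3), a log2 difference of -4.03 (SE 0.772, limma adjusted p = 0.0361, edgeR adjusted p = 0.0503). Its count was 133 ± 170 at 1 h, 200 ± 149 at 12 h and 385 ± 32.4 at 72 h (SD, n = 3), and at 12 h the libraries ranged from 36.0 to 326. ENSRNOG00000001806, lower at 1 h, was also lower at 6 h, with a log2 difference of -3.30 (limma adjusted p = 0.0324). The 37 features that rose at 6 h had median log2 differences from sham of 1.01 at 1 h, 2.04 at 12 h and 1.45 at 72 h, and 33, 36 and 34 of them lay above sham at these times. The 17 that fell had medians of -0.47, -1.13 and -0.46, with 13, 17 and 14 below sham. Because these features were called against the same sham libraries, unchanged groups would lie on the same side. For the 37, the medians at 1 h, 12 h and 72 h were 0.369, 0.743 and 0.527 of that at 6 h, where 100 simulations of unchanged groups gave 0.296 to 0.698, 0.317 to 0.654 and 0.287 to 0.706, with a median of 35 features above sham at each time. For the 17 they were 0.170, 0.405 and 0.165, against simulated ranges of 0.246 to 0.854, 0.197 to 0.749 and 0.25 to 0.718. The simulated features vary independently, which real ones do not, so these ranges are too narrow. edgeR called 55 features (39 higher, 16 lower) and DESeq2 648 (438 higher, 210 lower), and with the dominant features left out and equal totals 63 were higher and 14 lower, on a scale on which the median of all features lay -0.73 log2 units from sham. The count was 5, 5 and 1 without sham replicate 1, 2 and 3, and 0, 0 and 170 without 6 h replicate 1, 2 and 3, with adjusted p of up to 0.187 for ENSRNOG00000013973 and 0.162 for ENSRNOG00000030404 over their alternatives.

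At 12 h, 8 features differed from sham in limma, 6 higher and 2 lower, with a median size of 3.83 log2 units and a range of 1.91 to 5.48. ENSRNOG00000013280 rose from a normalised read count of 67.9 ± 49.1 in sham to 926 ± 595 at 12 h (SD, n = 3), a log2 difference of 3.80 (SE 0.564, limma adjusted p = 0.0335). It had also risen at 6 h, to 455 ± 270 (SD, n = 3, log2 difference 2.81, limma adjusted p = 0.0387), and its count was 20.3 ± 7.51 at 1 h and 25.9 ± 11.5 at 72 h (SD, n = 3). ENSRNOG00000013973 reached 1383 ± 1061 at 12 h (SD, n = 3, log2 difference 5.48, limma adjusted p = 0.0373), against 11.7 ± 13.04 at 1 h and 18.1 ± 3.21 at 72 h. The 2 features that were lower had log2 differences of -1.91 (SE 0.326, limma adjusted p = 0.0388) and -2.59 (SE 0.406, limma adjusted p = 0.0335). Of the features tested, 15.6% separated the groups completely, where chance gives 10%. edgeR called 6 features and DESeq2 313 (238 higher, 75 lower), with the dominant features left out and equal totals 10 were higher and 0 lower, and limma fitted to the sham and 12 h libraries alone called 0 (985 at unadjusted p under 0.05, adjusted p = 0.213 for ENSRNOG00000013280). The count was 3, 2 and 0 without sham replicate 1, 2 and 3, and 0, 0 and 1546 (812 higher, 734 lower) without 12 h replicate 1, 2 and 3, and the adjusted p of ENSRNOG00000013280 reached 0.247 over its alternatives.

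**Figure D3:**
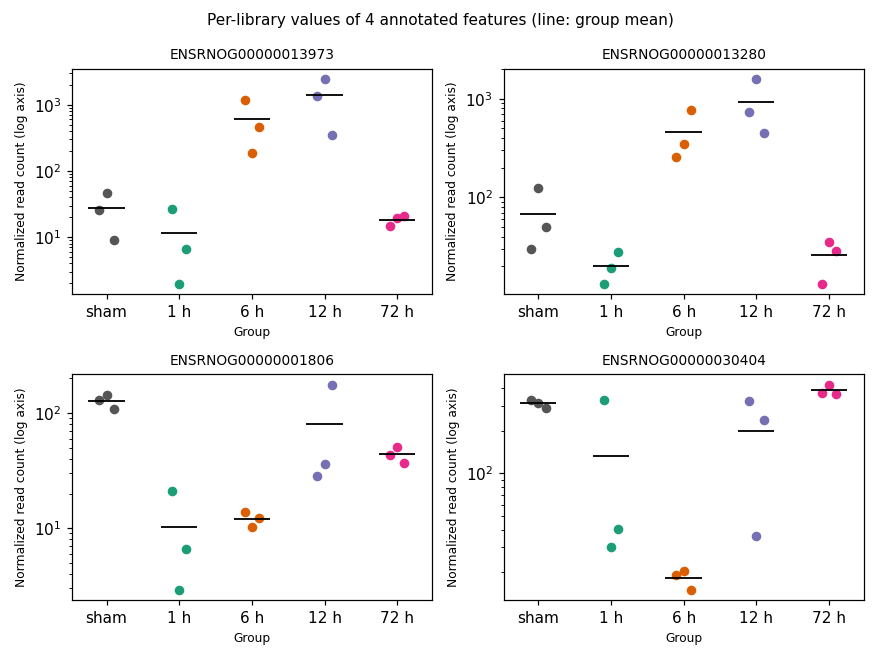
Normalised read count (vertical axis, log scale) of 4 annotated features in each library, by group (horizontal axis), with a line at the group mean. ENSRNOG00000013973 and ENSRNOG00000013280 are higher in all 6 h and 12 h libraries than in all sham libraries, ENSRNOG00000001806 is lower in all 1 h and 6 h libraries, and ENSRNOG00000030404 is lower in all 6 h libraries and spreads widely at 1 h and 12 h.

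The 6 h and 12 h differences from sham shared 6 called features, 5 higher and 1 lower at both times. Independent lists of these sizes would share 0.0200 higher and 0.00306 lower. In 100 simulations of unchanged groups against shared controls, the features with the smallest p, in lists of the same sizes, shared a median of 1 higher (at most 4) and 0 lower (at most 2). Across genes the log2 differences at 6 h and 12 h correlated with r = 0.714, where simulated unchanged groups gave 0.498. The covariance was 0.614 against a simulated 0.256, a difference of 0.358. The simulated values leave out any relation between 6 h and 12 h libraries other than sham, and deviations from the group means correlated by 0.132 to 0.448 in the 3 same-numbered pairs of these times. For 1 h the same difference in covariance was 0.0664 with 6 h, -0.00323 with 12 h and 0.0328 with 72 h, and for 72 h it was 0.175 with 6 h and 0.125 with 12 h. The sham group is too small to be split, so part of the excess in called features may come from the shared controls. Calls at 1 h shared 2 features with those at 6 h and 0 with those at 12 h.

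At 72 h no feature passed adjusted p 0.05 against sham in limma (0 of 11117, lowest adjusted p 0.281), with 806 at unadjusted p under 0.05. edgeR also called 0 (738 at unadjusted p under 0.05), and DESeq2 called 29, 18 higher and 11 lower. Of the features tested, 17.6% separated 72 h from sham completely, where chance gives 10%. The count was 3 without sham replicate 1, 1 without 72 h replicate 1 and 1 without 72 h replicate 3.

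Between 12 h and 6 h, both under run label C, limma called 0 features (423 at unadjusted p under 0.05, lowest adjusted p 0.214), edgeR called 0 (368 at unadjusted p under 0.05) and DESeq2 called 15, 8 higher and 7 lower. Complete separation held for 5.71% of features, where the mean over all splits is 10%. Without 12 h replicate 3 limma called 8, all lower at 12 h.

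Between 72 h and 1 h, both under run label A&B, 2 features were higher at 72 h in limma. An assembled feature had a log2 difference of 2.30 (SE 0.288, limma adjusted p = 0.00516) and an annotated feature had 2.65 (SE 0.418, limma adjusted p = 0.0475). Against sham the assembled feature was lower at 1 h (log2 difference -1.57, limma adjusted p = 0.0391) and had 0.73 at 72 h (limma adjusted p = 0.620). edgeR called 1 feature and DESeq2 71. The count was 14 and 0 without 1 h replicate 1 and 3, and 1, 1 and 0 without 72 h replicate 1, 2 and 3.

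The mean of 6 h and 12 h differed from the mean of 1 h and 72 h for 205 features in limma, 127 higher and 78 lower, with a median size of 1.45 log2 units. This is the contrast that run label and time share in full. Of the 205, 51 were assembled models (24.9% against 19.8% of the features tested, Fisher's exact p = 0.0761, adjusted 0.264). edgeR called 198 (140 higher, 58 lower) and DESeq2 618, and with the dominant features left out and equal totals 21 were higher and 4 lower. On that scale the median of all features lay at -0.20 log2 units, while the smallest called difference had been 0.81. All 205 kept their direction, which could hardly turn. Their median signed log2 difference went from 1.14 to 0.93 and its median SE from 0.30 to 0.47. The count was 93 without 72 h replicate 1, between 103 and 122 without 1 h replicate 2 or 3, 6 h replicate 1 or 2 or 12 h replicate 1, and 956 without 12 h replicate 3.

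With the log2 library factor as a covariate, a choice made after the data were examined, the counts against sham were 47 at 1 h (8 higher, 39 lower), 777 at 6 h (526 higher, 251 lower), 445 at 12 h (309 higher, 136 lower) and 23 at 72 h (19 higher, 4 lower). All 15, 54 and 8 features called without it at 1 h, 6 h and 12 h were also called with it. Between 72 h and 1 h it gave 199 features (112 higher, 87 lower), and between 12 h and 6 h 0, with 968 at unadjusted p under 0.05. The median SE of a difference at 6 h was 0.511 without the covariate and 0.411 with it. Calls at 6 h and 12 h then shared 269 features that were higher at both times and 51 that were lower, with 0 of opposite direction. Independent lists would share 14.6 and 3.07. Lists of the same sizes from simulated unchanged groups with shared controls had a median overlap of 103 higher (at most 119) and 37 lower (at most 52), so the overlap of lower features lay within the simulated range. At 6 h and 72 h the calls shared 16 features that were higher, where such lists shared a median of 11 and at most 16. In these simulations features vary independently and groups are related only through sham. Real 6 h and 12 h libraries also share a run label, so 269 against at most 119 does not tell a shared response from a shared label.

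**Figure D4:**
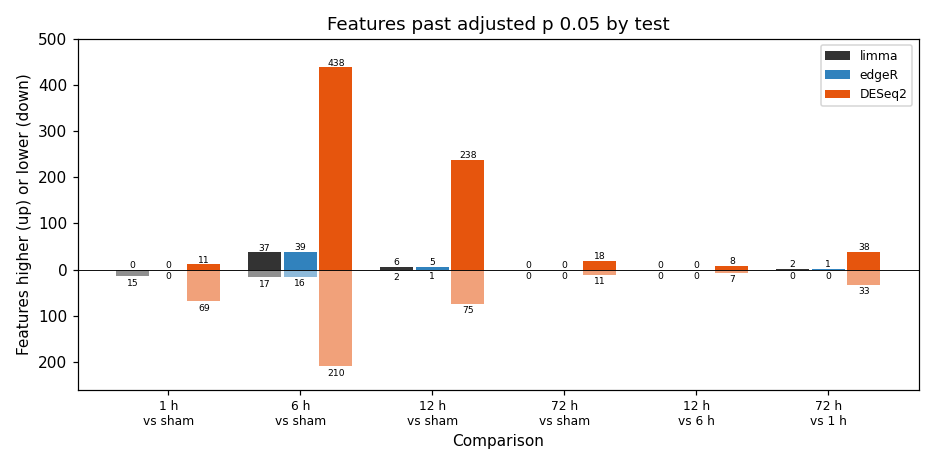
Number of features higher (bars up, solid) or lower (bars down, pale) past adjusted p 0.05 for each of 6 comparisons (horizontal axis) by limma on the deposited values and by edgeR and DESeq2 on the recovered reads. In all 3 tests 6 h against sham has the most features, with 54 in limma, 55 in edgeR and 648 in DESeq2. DESeq2 was run on all features with reads, limma and edgeR on those that passed the filter.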

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

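The tests of the library factor, of the first principal component and of the 72 h level of the features that fell at 1 h, and the fits with TMM scaling, with the library factor and with equal totals, were chosen after the results they bear on were seen. Counting other splits of the same libraries was set beforehand, and its repeat with the library factor in the fit was added.

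The 6 h and 12 h libraries differed from the 1 h and 72 h libraries for 205 features (127 higher, 78 lower), which was singled out because the difference between time points was itself tested. Merged into 1 group each, these 12 libraries gave 186 features. Of 100 splits 1 (the real one) reached that count, and the highest other had 17. With the log2 library factor in the fit the values were 1091, 1 of 100 and 5. The other splits broke up the time groups, which the real split keeps whole, so any difference among the groups favours it. They argue against a random mix of single libraries and cannot test how the groups pair up. Adding the library factor to the fit could not test it as a source. The median signed log2 difference of the 205 features, rises and falls together, was 1.138 without the factor and 1.136 with it. The mean log2 factor was -0.0489 at 6 h and 0.0958 at 12 h, against -0.0901 at 1 h and -0.0688 at 72 h. Means this close leave the factor little room to move a difference, so the median could hardly change. The count rose to 1473 with the factor in the fit. Since the median SE of the 205 went from 0.296 to 0.238, that rise is no evidence by itself. A difference between run labels cannot be told apart from time. Sham shares the label of 1 h and 72 h. Its median position between their level (0) and that of 6 h and 12 h (1) was 0.304, with quartiles of 0.0553 and 0.635. The 205 features were chosen for a gap between these levels and not by sham, so a pure label effect can put sham above 0. How far above was not computed, and a pure time course sets no value. Both a passing response at 6 h and 12 h and a run difference may contribute, and the size of either stays open.

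Libraries of the same group lay far apart along the first principal component, which followed the library factor, in part by construction. Sequencing depth is argued against by a Spearman correlation of 0.136 with total reads (permutation p = 0.630). The 5 dominant features taking most of the reads are argued against as the whole source, since the SD of the log2 factor fell only to 0.888 of its value once the reads outside them were used, although within groups their total share correlated with the component (r = 0.892). Time group cannot set libraries of the same group apart, and no biological explanation was tested. A candidate explanation that stays open is a difference between samples in how reads divide between abundant and rare features. It could arise through RNA quality, library preparation or cell content. None of these was tested, and a test of cell content would need gene names.

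All 15 features called at 1 h against sham were lower. Whether scaling contributes was not decided: the share of falls among called features was at least 0.944 under TMM scaling (18 features) and quantile normalization (11 features), but these move the 15 features by at most 0.07 and 0.33 log2 units, too little to turn falls of 1.57 or more. With the dominant features left out and equal totals no feature was called. All 15 still lay below sham, but the median of all features also lay at -0.40 log2 units there, so they could hardly turn. Their median log2 difference went from -2.43 to -2.87, mostly through this shift. Its median SE went from 0.42 to 0.69, so the call ended through the larger spread. In the 10 splits of the 6 libraries, too few for a share under 0.05, 1 split (the real one) gave 15 features and the highest other 0. A fall of these transcripts within 1 h of modelling stays open as a hypothesis, since the splits are too few to test chance; edgeR called 0 features but gave ENSRNOG00000001806 a fall of similar size (log2 difference -3.73, adjusted p = 0.0629).

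An assembled feature was higher at 72 h than at 1 h by 2.30 log2 units (SE 0.288, limma adjusted p = 0.00516), which was singled out by the test between these times. An annotated feature was higher at 72 h than at 1 h by 2.65 log2 units (SE 0.418, limma adjusted p = 0.0475), singled out in the same way.

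For the other comparisons each pair of groups has 10 splits, too few for a share under 0.05. At 6 h against sham the real split gave 54 features and the highest other 1, and at 12 h against sham these were 8 and 1. At 72 h against sham they were 0 and 0, so all 10 splits gave as many, and for 72 h against 1 h they were 2 and 2, reached by 2 splits. For 12 h against 6 h the real split gave 0, and the split of 6 h replicate 1 and 12 h replicates 1 and 2 against the rest gave 172. The library factors of the former were 0.729, 0.782 and 0.584, all below those of the rest (0.886, 1.40 and 2.67). With the log2 library factor in the fit no other split gave more than 2. Since this split divides the libraries by their factors, the factor in the fit takes up most of its difference. The fall in count is therefore no separate evidence, and the split was picked as the highest. With the log2 library factor in the fit the real and highest other counts were 47 and 1 at 1 h, 777 and 1 at 6 h, 445 and 1 at 12 h, 23 and 0 at 72 h, 0 and 2 for 12 h against 6 h, and 199 and 2 for 72 h against 1 h. No test of single outlying libraries was run, and array weights and fits with 1 library left out are given below.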

How the results depend on the processing

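TMM scaling, the library factor as a covariate, equal totals without the dominant features, array weights and the fit within run label A&B were chosen after the data were examined. Counts follow the order 1 h, 6 h, 12 h and 72 h against sham, 12 h against 6 h, 72 h against 1 h, and 6 h and 12 h against 1 h and 72 h. As reported they were 15, 54, 8, 0, 0, 2 and 205. The 4 printed features kept their direction in all 22 or 23 alternatives each, and were called in 16 (ENSRNOG00000013973), 15 (ENSRNOG00000013280), 15 (ENSRNOG00000001806) and 15 (ENSRNOG00000030404) of them, with log2 ranges of 3.62 to 4.97, 3.29 to 4.34, -4.55 to -2.86 and -4.73 to -3.51. These features were picked as the largest called differences, and all alternatives reuse the same libraries, so their direction could hardly turn. The recomputed factors and the 2-fold minimum, which could not change these results, are among the alternatives counted. The causes of the changes in count below were not tested, except where stated.

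Counts stayed within 1.5 times for all comparisons under TMM scaling and the 2-fold minimum; recomputed median-of-ratios factors are the deposited ones and move nothing. Fits to the libraries compared alone gave 112, 494, 0 (985 at unadjusted p under 0.05), 11, 0, 14 and 121, and run label A&B alone gave 106 at 1 h, 2 at 72 h and 39 for 72 h against 1 h. Without a filter the counts were 33 at 6 h, 5 at 12 h and 7 for 72 h against 1 h, and with a minimum 5 times as high 5 at 12 h. A pseudocount of 0.5 gave 4 for 72 h against 1 h, and a pseudocount of 10 gave 99 at 6 h and 5 for 72 h against 1 h. Quantile normalization gave 206 at 6 h, 13 at 12 h and 1 for 72 h against 1 h. Limma without trend or robust fitting gave 4, 7, 1, 0, 0, 3 and 126, with 1 higher and 3 lower at 1 h, 2 and 5 at 6 h, and 0 and 1 at 12 h; of the features called as reported, 0 of 15, 6 of 54 and 0 of 8 were among them. DESeq2 gave 80, 648, 313, 29, 15, 71 and 618, and edgeR 0, 55, 6, 0, 0, 1 and 198. The library factor as a covariate gave 47, 777, 445, 23, 0, 199 and 1473. Equal totals without the dominant features gave 0, 77, 10, 1, 0, 0 (551 at unadjusted p under 0.05) and 25, with median shifts of all features from sham of -0.40, -0.73, -0.54 and -0.41 log2 units. Array weights, from 0.202 for 12 h replicate 3 to 4.34 for 12 h replicate 1, gave 352, 1223, 3604 (1688 higher, 1916 lower), 108, 192, 228 and 1753.

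With 1 library left out the counts ranged from 0 to 10 at 1 h, 0 to 170 at 6 h, 0 to 1546 at 12 h, 0 to 3 at 72 h, 0 to 8 for 12 h against 6 h, 0 to 14 for 72 h against 1 h and 93 to 956 for the contrast of 4 times. The highest at 12 h, 1546, and the highest of the contrast, 956, came without 12 h replicate 3, and 170 at 6 h came without 6 h replicate 3.

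The replicate number as a block gave 12, 123, 15, 0, 0, 1 and 214. The numbers were not taken to pair the samples, although the check was mixed: of 30 pairs with the same number 14 had deviations correlated above 0.1 (median 0.0802, range -0.328 to 0.448), and 6 of 15 libraries correlated best with their own number. Between 6 h and 12 h all 3 pairs exceeded 0.1 (0.132 to 0.448), where the block changed no call (0 features), and replicate 3 had the highest library factor in 4 of the 5 groups.

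Not run were the alternative without haemoglobin genes and the set tests with an estimated correlation, which need gene names. Depth limits the comparisons to features with reads among the 4.67 to 7.65 M reads outside the dominant features.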

Other observations

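The correlations among dominant features, the search for features that differ within groups or share reads, the level per library and the simulated ratio were chosen after the data were examined, and the test of the 6 h features at 12 h was set before its result was seen.

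The shares of some dominant assembled features were related from library to library. Over 15 libraries the shares of features 3 and 4 correlated with r = 0.963 (permutation p = 1e-05, the smallest the resamples can give, adjusted 4e-05 over 4 relations) and rho = 0.932 (permutation p = 1e-05, adjusted 4e-05). Without the 2 farthest libraries r was 0.955, and within run labels A&B and C it was 0.979 and 0.947. The ratio of their shares stayed between 2.36 and 3.40 while the sum ran from 5.86% in sham replicate 2 to 20.6% in 6 h replicate 2. Features 2 and 3, whose assembled models carry consecutive numbers, were opposed, with r = -0.661 (permutation p = 0.00757, adjusted 0.0101) and rho = -0.589 (permutation p = 0.0233, adjusted 0.0311), -0.589 without the 2 farthest libraries, and -0.881 and -0.903 within the run labels. Features 1 and 3 gave r = -0.756 (permutation p = 0.00089, adjusted 0.00178) and rho = -0.682 (permutation p = 0.00603, adjusted 0.0121), -0.639 without the 2 farthest libraries and -0.837 and -0.875 within the run labels. Shares of the same total oppose each other in part by construction. Features 1 and 2 gave r = 0.0998 (permutation p = 0.726, adjusted 0.726) and rho = 0.0857 (permutation p = 0.761, adjusted 0.761), 0.0756 without the 2 farthest libraries and 0.572 and 0.837 within the run labels.

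Of 578 features with a mean value of at least 1000, 9 differed at least 32-fold between libraries of the same group. For some of the 9 the range came from a 0 in a library where another assembled model, with nearly the same values elsewhere, held reads. Such a range need not reflect the samples. In 3 pairs of tested features both members had the same number of reads in at least 10 libraries, counting only libraries with 10 or more reads on each, and in 2 of these pairs a member was at 0 in a library where the other was not. None of the 6 features in these pairs was among the limma calls (0 of 15 at 1 h, 0 of 54 at 6 h, 0 of 8 at 12 h, 0 of 205 in the contrast of 4 times).

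The hypothesis that features called at 6 h also differ at 12 h was tested in the 12 h, 1 h and 72 h libraries, which entered the 6 h calls only through the shared variance. At 12 h the 54 features differed from 1 h and 72 h in the direction of the 6 h call by a median of 0.95 log2 units, 46 of 54 in that direction. The one-sided exact permutation p over the 84 splits of the 9 libraries was 0.0357, with a highest other split of 1.19. The values may reflect a response that lasts from 6 h to 12 h, and a difference between run labels, which 12 h shares with 6 h, gives the same values. Deviations from the group means also correlated by 0.132 to 0.448 in same-numbered 6 h and 12 h libraries, which the permutation p leaves out.

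Levels of the 6 h features differed between the 12 h libraries. For the 100 features with the smallest p at 6 h against sham, chosen without the library scored, the mean log2 difference from sham in the direction of the 6 h difference was 2.29 and 2.69 in 12 h replicates 1 and 2 and 0.40 in replicate 3. Replicate 3 also had the largest library factor (2.67) and the lowest array weight (0.202) of all 15 libraries, and whether its low level reflects the sample, the quality of the library or its label was not settled. It was 2.10, 2.22 and 1.55 in the 6 h libraries, 1.47, 0.72 and 1.77 in the 72 h libraries, 1.15, 0.71 and 0.76 in the 1 h libraries, and 0.94, 0.54 and 0.24 in the sham libraries.

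The hypothesis that the 15 features lower at 1 h are lower there than at 72 h could not be decided. Their median difference from sham at 72 h was 0.390 of that at 1 h, and simulated unchanged groups with the same sham libraries gave ratios of 0.223 to 0.873 (median 0.5 over 100 simulations).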
